A study of Pinus pinaster with 12 samples.

How the data were processed

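RNA was measured in roots of maritime pine (Pinus pinaster) seedlings aged 1 month, collected 24 h after irrigation with 80 mL of water or of 3 mM ammonium chloride. Per the labels' protocols, seedlings had 3 days of acclimation, and the experiment was run 3 independent times. Total RNA with an integrity number above 7 gave polyadenylated RNA, of which 3.15 to 6 µg was fragmented and precipitated with an antibody against N6-methyladenosine (m6A), a methylated base of messenger RNA. Fragmented RNA that had not been precipitated served as input. Each of the 4 groups (input with water, input with ammonium, m6A immunoprecipitate (IP) with water, IP with ammonium) had 3 libraries, and each library's group and number came from its title.

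The table deposited by the authors held whole-number read counts per transcript ID for each of the 12 libraries, without normalization. Per the submitters' processing notes, bcl2fastq and BWA were used. The library kit and strandedness, and whether IP and input libraries were made alike, are not given in the sources used here, so the IP/input ratios could also carry differences in library making. The versions, the reference sequences, the rule for counting reads that match several transcripts and any removal of duplicate reads are not given in the sources used here. Transcripts that share sequence could therefore share reads, and a gene split over several transcript IDs enters the tests several times. The table held 253670 transcripts, of which 16801 had no read in any library. Library totals ran from 57945305 to 81534388 counts. The ammonium IP libraries were deeper than the water IP libraries, which gives the ammonium comparisons and the ammonium peak list more reads.

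The authors also deposited a peak list for each treatment. Per the file headers, each peak has a fold enrichment, which is a ratio of IP over input, and a p-value, and both are the authors' own values. The peak caller and its settings are not given in the sources used here, and each list stands for all libraries of its treatment, so peaks had no replicates. Peak positions are counted from 1 along the transcript ID. The files do not pair transcript IDs with gene names, and no genome was used here, so gene lists and cell type markers planned for the study (ammonium assimilation, m6A writers and erasers, shoot markers and others) were not tested, and peaks were not placed in exons or untranslated regions.

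Counts were tested with edgeR 4.0.16 in R 4.3.3, with trimmed mean of M-values scaling, the default expression filter (minimum count 10, minimum total 15), robust quasi-likelihood fits and two-sided F tests. Benjamini-Hochberg adjustment was made over all transcripts tested, and a transcript was called at an adjusted p under 0.05. Of the 5 comparisons, 4 used only the 6 libraries of their groups (ammonium against water in the input and in the IP, IP against input in each treatment). The comparison of the IP/input ratio between treatments used all 12 libraries as 4 group means and tested their interaction. A log2 fold change is given with its standard error (SE). Levels of single transcripts are CPM, counts divided by the library total and scaled, with the standard deviation (SD) of 3 libraries. Groups of transcripts were tested with fry and camera of limma 3.58.1, the latter with a preset correlation of 0.01 and with an estimated correlation, and p was adjusted over the groups tested together (3 peak classes, or 2 lists called in the input).

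Peaks of the lists were called shared when they overlapped by at least 1 base on the same transcript, with bedtools 2.31.1. A transcript's peak class was shared, water only, ammonium only or no peak. Intervals of shares are 95% Wilson intervals and cover counting error only. Medians of ratios have 95% intervals from 2000 bootstrap draws over transcripts, and matched comparisons used 10000 draws within 50 bins of abundance. Principal components were taken from log2 CPM of the transcripts that passed the filter over all 12 libraries.

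Transcripts to be named were chosen by a rule set before the data were examined: the 2 with the smallest p in each direction among called transcripts whose groups did not overlap, or, where no transcript was called, the 1 with the smallest p in each direction. For peaks, the highest fold in each list and the highest fold without overlap in the other list were named. Alternatives set before the data were examined were size factors of the DESeq2 type, library size scaling, DESeq2 1.42.0, no filter, a filter of 50 reads in 3 libraries, a block for the replicate number, fits without robust estimation, a fit of all 12 libraries, omission of each library in turn, and stricter peak and overlap rules. Chosen after seeing the data were limma's voom with sample weights and adjustment over shorter lists of transcripts.

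Pairs of libraries of 1 group were compared by chi-square of their counts. The statistic per degree of freedom ran from 11.9 to 62.1 over the 12 pairs, far above sampling noise, so no library was counted as a repeat of another. The labels do not say whether libraries of the same number came from the same RNA, and they give no sequencing batch.

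The tests were tried on simulated counts with the library sizes and fitted spread of the real libraries. Per comparison, 60 transcripts were changed 2-fold, 70 were changed 4-fold and 70 were changed 16-fold. Means were otherwise averaged over the groups compared (for the ratio, over treatments within input and within IP), so no other transcript changed. In the real data most transcripts were called for IP against input, so the shares recovered there do not give the power of those real tests. For ammonium against water in the input (110351 transcripts), 25% of 2-fold, 71.4% of 4-fold and 88.6% of 16-fold changes were recovered. In the IP (93348 transcripts) the shares were 3.33%, 22.9% and 68.6%. For IP against input they were 0%, 4.29% and 50% in water (120291 transcripts) and 18.3%, 54.3% and 88.6% in ammonium (116468 transcripts). For the change of the IP/input ratio (140660 transcripts) they were 0%, 11.4% and 48.6%, so most changes of 4-fold or less in this ratio would have gone uncalled. Of the simulated calls for ammonium in the input, 25 of 152 were false; in the order given above, the other comparisons had 9 of 75, 2 of 40, 19 of 130 and 0 of 42. In 3 of the 5 comparisons the false share thus lay above the threshold of 0.05.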

Results

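Root RNA of maritime pine seedlings was profiled 24 h after irrigation with water or 3 mM ammonium chloride, as input RNA and after precipitation with an antibody against m6A. The series asks which transcripts carry m6A in roots and how ammonium supply changes their abundance and methylation. The totals ran from 69030249 to 81534388 counts in the water inputs, 74257255 to 79703198 in the ammonium inputs, 57945305 to 63522543 in the water IP and 65539363 to 73185176 in the ammonium IP, with 3 libraries each. Levels of single transcripts are in CPM, the count scaled to the library total. The p-values measure the spread between the 3 libraries of a group, which the labels describe as 3 independent runs of the experiment.

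Transcripts with an m6A peak took a larger share of reads in the IP than in the input. The 7077 transcripts with a peak in either deposited list took 15.6% ± 0.371 of the reads of the water inputs and 15.8% ± 0.0796 of those of the ammonium inputs (SD, n = 3). In the IP they took 31.8% ± 1.82 with water and 34.2% ± 0.299 with ammonium (SD, n = 3). The 6 IP libraries lay 17.3 percentage points above the 6 inputs (p = 0.00216, two-sided exact permutation test, the smallest that 924 splits allow). The splits ignored treatment and any RNA shared by IP and input. Peaks and counts came from the same libraries, so this share describes the lists and is no independent test of them. Between treatments the IP differed by 2.39 percentage points (p = 0.1 in a two-sided exact permutation test, the smallest p that 3 against 3 libraries allow), but by 1.33 without replicate 1 of the water IP. The inputs differed by 0.159 percentage points (p = 0.5 in the same exact test), by 0.369 without replicate 2 of the water inputs and by 0.0899 and 0.0182 without replicates 1 and 3 of these.

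IP and input separated on the first principal component, which held 85.6% of the variance, against 3.10% for the next. Replicate 1 of the water IP stood apart, with a score of 348.8 where the other IP libraries scored 598 to 744. On the second component it scored 357.3, where all other libraries scored -103.8 to 17.0, so it was not simply intermediate between IP and input. Its log2 levels correlated with those of the inputs across transcripts at a mean r of 0.600, against 0.346 to 0.478 for the other IP libraries (transcripts are not independent replicates).

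**Figure D1:**
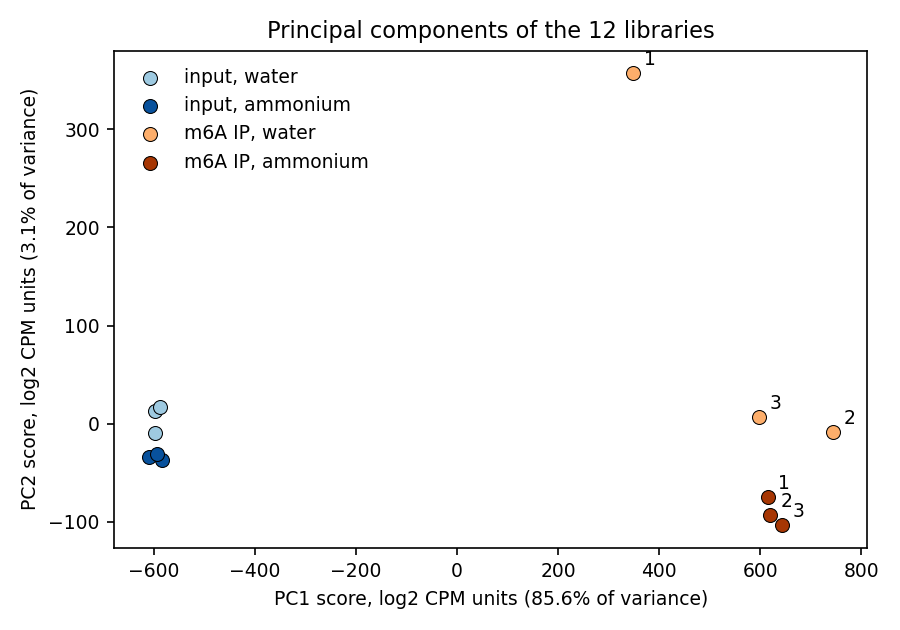
Scores of the 12 libraries on the first 2 principal components of log2 CPM, with 1 point per library, colours for the 4 groups and replicate numbers beside the IP libraries. The inputs lie together on the left. On the horizontal axis replicate 1 of the water IP, at 348.8, lies between them and the other IP libraries. On the vertical axis it lies apart from all others, at 357.3.

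In the input, 487 of 114887 transcripts tested were called for ammonium against water with edgeR, and most of these were higher. There were 440 higher transcripts, 281 of them at least 2-fold, with a median log2 fold change of 1.13. The 47 lower transcripts had a median log2 fold change of -2.41, and 37 of them were at least 2-fold lower. The transcript pp_235803 rose from 2.11 ± 0.185 to 12.3 ± 2.44 CPM (SD, n = 3), a log2 fold change of 2.60 (SE 0.17), and pp_181095 rose from 9.76 ± 0.576 to 28.8 ± 3.43, a log2 fold change of 1.61 (SE 0.11). In the other direction, pp_1921 fell from 6.74 ± 1.07 to 0.433 ± 0.148 CPM (log2 fold change -3.90, SE 0.25) and pp_166457 from 4.46 ± 0.991 to 0.234 ± 0.0688 (log2 fold change -4.20, SE 0.29). All 4 had an adjusted p of 0.00161 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, and none of the 4 carried an m6A peak in either list. The higher transcripts included every ID from pp_235799 to pp_235812, with pp_235803 among them. IDs of such runs could share reads, so the 440 are uncertain as separate transcripts. In the simulated counts, 25 of 152 calls of this comparison were false, so more than the nominal share of the 487 could be false.

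An unadjusted p under 0.05 was reached by 11895 transcripts (10.4%), and the groups did not overlap at 16.6% of the transcripts, where chance gives 10% for 3 against 3. The number of called transcripts moved strongly with single libraries: it was 39, 90 and 250 without replicates 1, 2 and 3 of the water inputs, and 4921, 305 and 228 without replicates 1, 2 and 3 of the ammonium inputs. The excess of higher over lower calls moved too: without replicate 1 of the ammonium inputs 2494 were higher and 2427 lower, with DESeq2 2044 and 799 and with voom and sample weights 1892 and 1168. The number was 2843 with DESeq2 and 0 in a fit of all 12 libraries, whose shared spread includes that of the IP, and in that fit none of the 4 named transcripts passed (adjusted p from 0.131 to 1).

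**Figure D2:**
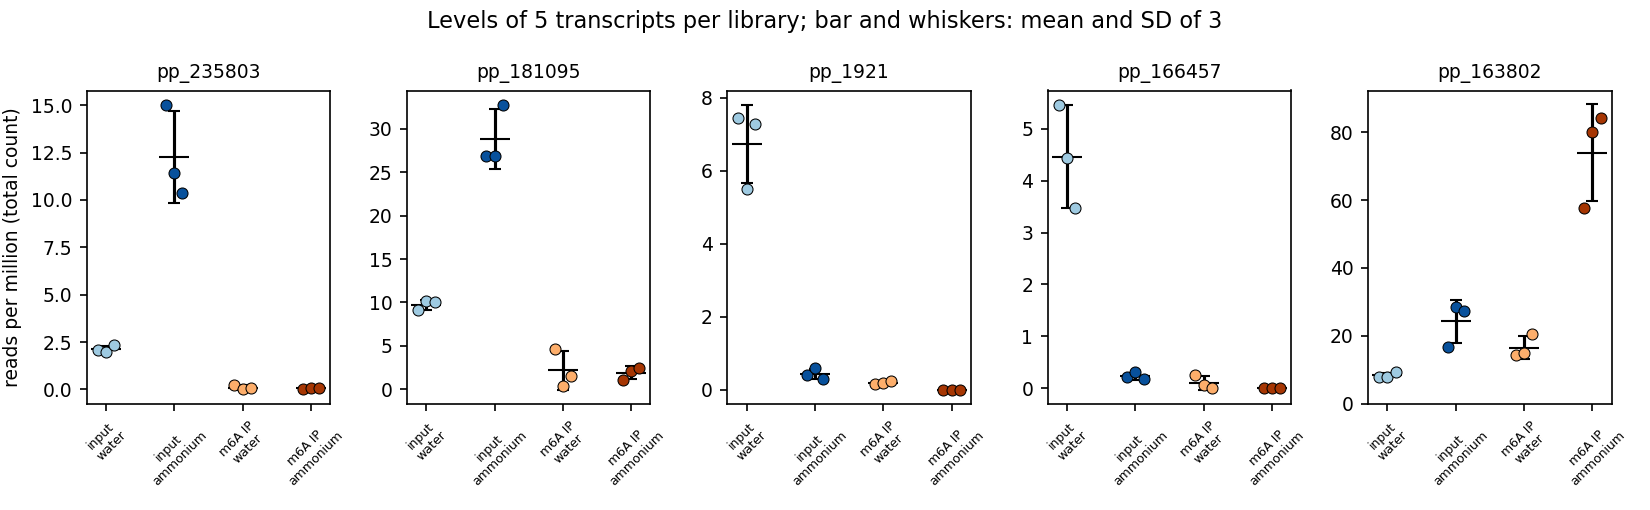
CPM of the library total for 5 transcripts, with 1 point per library and the mean and SD of 3 libraries per group as a horizontal mark and whiskers; each panel has its own vertical scale. In the inputs pp_235803 rose with ammonium from 2.11 to 12.3 and pp_1921 fell from 6.74 to 0.433, and in the IP pp_163802 stood at 16.6 with water and 73.9 with ammonium, without passing the adjusted threshold.

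In the m6A IP, no transcript out of 99846 passed for ammonium against water with edgeR. The smallest adjusted p, 0.0717, belonged to pp_163802, with a log2 fold change of 2.35 (SE 0.23) and 16.6 ± 3.43 CPM with water against 73.9 ± 14.3 with ammonium (SD, n = 3). This transcript had a peak in the ammonium list only, and its input level was 8.47 ± 0.769 with water and 24.3 ± 6.41 with ammonium. In the lower direction, pp_141822 had 8.16 ± 5.74 CPM with water and 0.488 ± 0.0664 with ammonium (log2 fold change -3.80, SE 0.50, adjusted p = 0.308). An unadjusted p under 0.05 was reached by 10431 transcripts (10.4%).

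The spread between IP libraries was larger, with a coefficient of biological variation of 0.480 against 0.238 in the inputs. It lay mostly in the water IP: the coefficient was 0.471 for IP against input in water and 0.272 in ammonium. Chi-square per degree of freedom was 39.8 to 62.1 for pairs of water IP libraries. For pairs of ammonium IP libraries it was 15.5 to 26.7, within the range of the input pairs (11.9 to 33.8). DESeq2 called 316 transcripts in the IP (160 higher, 156 lower), voom with sample weights 9, edgeR with the replicate number as a block 8 and the fit of all 12 libraries 879, and 34 passed with edgeR without replicate 2 of the water IP. Both pp_163802 and pp_141822 passed with DESeq2, without a filter, with the replicate block (adjusted p = 0.00344 and adjusted p = 0.0272), in the fit of all 12 libraries and without replicate 2 of the water IP.

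The ammonium responses seen in the input were followed into the IP. Of the 440 transcripts higher in the input, 316 were tested in the IP, where their median log2 fold change was 0.14 and 58.2% had the sign of the input change; the median of all tested IP transcripts was -0.23. As a group they did not pass (fry adjusted p = 0.351, and camera adjusted p = 1.22e-13 with the preset correlation but adjusted p = 0.269 with an estimated correlation). Without replicate 1 of the water IP their median log2 fold change was 0.72 (fry adjusted p = 0.0748) and 91.1% had the sign of the input change, whereas without replicate 2 it was -0.16 (fry adjusted p = 0.877; 43.2% with the sign) and without replicate 3 it was -0.03 (fry adjusted p = 0.613; 49.1% with the sign). Omission of 1 ammonium IP library gave 0.28, 0.07 and 0.19 for replicates 1, 2 and 3. Of the 47 transcripts lower in the input, 18 were tested in the IP and 17 of these were lower there too, with a median log2 fold change of -1.74 (fry adjusted p = 0.0927, and camera adjusted p = 0.119 with an estimated correlation). Without replicate 1 of the water IP the median of the lower transcripts was -0.97 (fry adjusted p = 0.0748), and without replicate 2 it was -2.10 and the group passed (fry adjusted p = 0.0212).

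When p was adjusted over the 334 input-called transcripts tested in the IP, 33 passed in the IP (30 higher, 3 lower), among them pp_163802. This list was chosen on inputs that could share RNA with the IP libraries, so the count is not independent evidence. The list also held IDs of close number with near-equal values, such as pp_163802 and pp_163804 (log2 fold changes 2.35 and 2.44), which could share reads and are uncertain as separate transcripts.

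Across 68118 transcripts tested in both, the ammonium changes of input and IP correlated at a Pearson r of 0.275 and a Spearman rho of 0.274. Transcripts are not independent replicates, and IP and input of a seedling group could share RNA. In the 9 other relabellings of the treatment that kept IP and input of each number together, r ran from -0.0792 to 0.251, and the highest covariance was 0.0743, close to the 0.0823 of the real labels.

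**Figure D3:**
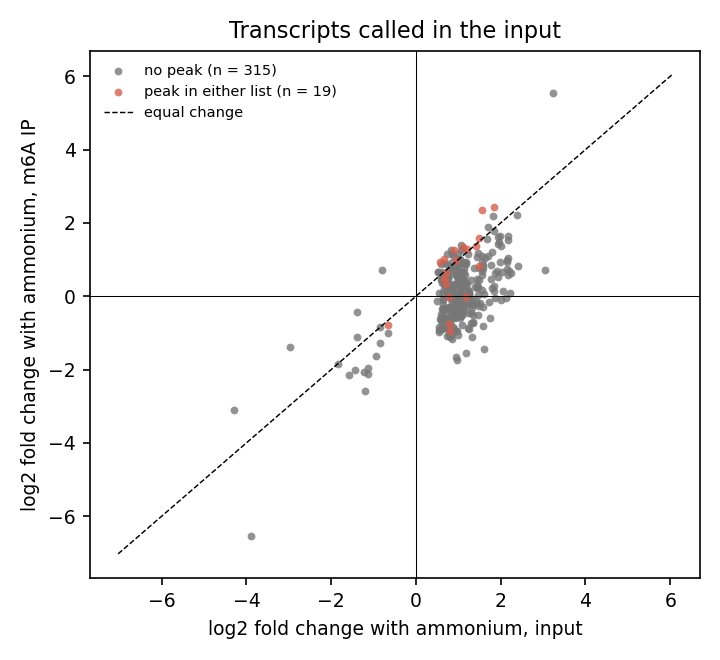
Fitted log2 fold change with ammonium in the input (horizontal) and in the m6A IP (vertical) for the 334 transcripts called in the input and tested in the IP, with 19 that carry a peak in colour and a dashed line at equal change. The higher transcripts lie around a median IP change of 0.14, and 17 of the 18 lower transcripts lie below 0 in the IP; the lowest point, pp_1921, had 0 reads in the ammonium IP, so its fitted value is no estimate of size.

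IP and input differed at most transcripts of the water-treated roots. Of 127525 transcripts tested, 45735 were higher in the IP and 41337 lower. Among the highest by p, pp_160188 stood at 895 ± 76.5 CPM in the IP and 50.2 ± 0.560 in the input (log2 fold change 4.69, SE 0.13), and pp_196331 at 134 ± 18.2 and 2.38 ± 0.101 (log2 fold change 6.34, SE 0.17). On the lower side, pp_200207 had 1.41 ± 0.209 CPM in the IP and 333 ± 28.6 in the input (log2 fold change -7.35, SE 0.19), and pp_200208 had 1.43 ± 0.329 and 176 ± 13.0 (log2 fold change -6.42, SE 0.19). The adjusted p of all 4 was 1.36e-05 in edgeR's quasi-likelihood test (n = 3 per group), and none of the 4 had a peak. The IDs pp_200207 and pp_200208 are adjacent and could share reads.

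The ammonium-treated roots gave the same kind of contrast, with 46925 transcripts higher and 60130 lower in the IP among 123957 tested. The transcript pp_141540, which carried a peak in both lists, had 3625 ± 42.3 CPM in the IP and 76.9 ± 5.04 in the input (log2 fold change 6.10, SE 0.12). Without a peak, pp_111048 had 753 ± 43.2 and 2.00 ± 0.366 (log2 fold change 9.10, SE 0.18). The largest drops by p were those of pp_211515, from 1205 ± 61.5 in the input to 1.28 ± 0.213 in the IP (log2 fold change -9.33, SE 0.18), and of pp_200207 (log2 fold change -7.73, SE 0.16). The adjusted p of all 4 was 1.52e-09 in edgeR's quasi-likelihood test (n = 3 per group).

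The contrast was much alike in both treatments, which share no library. Of 116941 transcripts tested in both, 40190 were higher in the IP of both, where independent lists would share 15470, and 38738 were lower in both, where independent lists would share 19277. Only 8 were called in opposite directions, and the log2 IP/input values correlated across transcripts at a Pearson r of 0.944 and a Spearman rho of 0.962. The 30008 transcripts at least 4-fold higher in both took 7.72% ± 0.239 and 7.79% ± 0.139 of input reads with water and ammonium, and 52.2% ± 5.21 and 53.6% ± 0.367 of IP reads (SD, n = 3). The 10472 at least 16-fold lower in both took 14.8% ± 0.154 and 14.5% ± 0.0150 of input reads and 0.325% ± 0.264 and 0.151% ± 0.0125 of IP reads (SD, n = 3); the water IP value rests on replicate 1, at 0.626% where replicates 2 and 3 had 0.130% and 0.219%. These groups were picked by the same counts, so the shares give their size and no test.

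The count of lower transcripts in water depended on replicate 1 of the water IP: without it, 50543 transcripts were higher and 60283 lower. Library size scaling moved the median log2 fold change of all transcripts from -0.30 to -0.80 in water, from -0.74 to -1.28 in ammonium, from -0.23 to -0.45 for ammonium in the IP and from -0.22 to -0.50 for the change of the ratio, so values are read against the median of all transcripts.

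The authors' deposited peak lists held 6637 peaks on 5968 transcripts with water and 6589 peaks on 6075 transcripts with ammonium. In the authors' deposited table for water the median fold enrichment was 11.7 and the median width 196 bases, and in that for ammonium 12.7 and 198 bases. The highest fold in the water list, 1370, belonged to a peak at positions 580 to 1063 of pp_136638, and the highest in the ammonium list, 2270, to a peak at positions 3131 to 3578 of pp_172319, both with an overlapping peak in the other list. Among peaks without overlap in the other list, the highest folds were 341 at positions 144 to 335 of pp_252409 with water and 346 at positions 1000 to 1500 of pp_112491 with ammonium, in the authors' deposited tables.

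Most peaks were shared between treatments. Of the water peaks, 81.3% (80.3 to 82.2) overlapped an ammonium peak, and of the ammonium peaks 80.9% (79.9 to 81.8) overlapped a water peak. By transcript, 4966 had a peak in both lists, 1002 in the water list only and 1109 in the ammonium list only. Among the 148273 transcripts that passed the count filter, independent lists would share 245 (odds ratio 641, 95% interval 581 to 686, Fisher's exact test), a value that describes these lists and not replicates. Shared peaks had a median fold of 15.7 in the water list and 17.3 in the ammonium list, and peaks of 1 list only had 4.37 and 4.75. With no replicates and deeper ammonium IP libraries, a peak absent from a list is not shown to be absent from that treatment.

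Transcripts with peaks stood above the others in the IP/input counts. Peaks and counts came from the same libraries, so this describes the lists and is no independent test of the peaks. In water the median log2 IP/input was 1.90 for transcripts with shared peaks (SD of 3 replicates 0.23), 3.81 for water-only peaks (SD 0.38), 2.46 for ammonium-only peaks (SD 0.35) and -0.50 for transcripts without a peak (SD 0.39). In ammonium the medians were 2.02 (SD 0.05), 3.33 (SD 0.18), 2.63 (SD 0.23) and -1.06 (SD 0.04) in the same order. These medians are of fitted values, but each SD is of 3 medians of log2 CPM differences between IP and input of the same number. The labels do not state that pairing. For water-only peaks in water these 3 medians were 3.23, 3.91 and 3.26. With the filter of 50 reads in 3 libraries the medians for water-only peaks fell to 2.52 in water and 2.20 in ammonium, where ammonium-only peaks then stood higher, at 2.31. Transcripts with a peak in 1 list only had medians above those without a peak in the other treatment too.

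**Figure D4:**
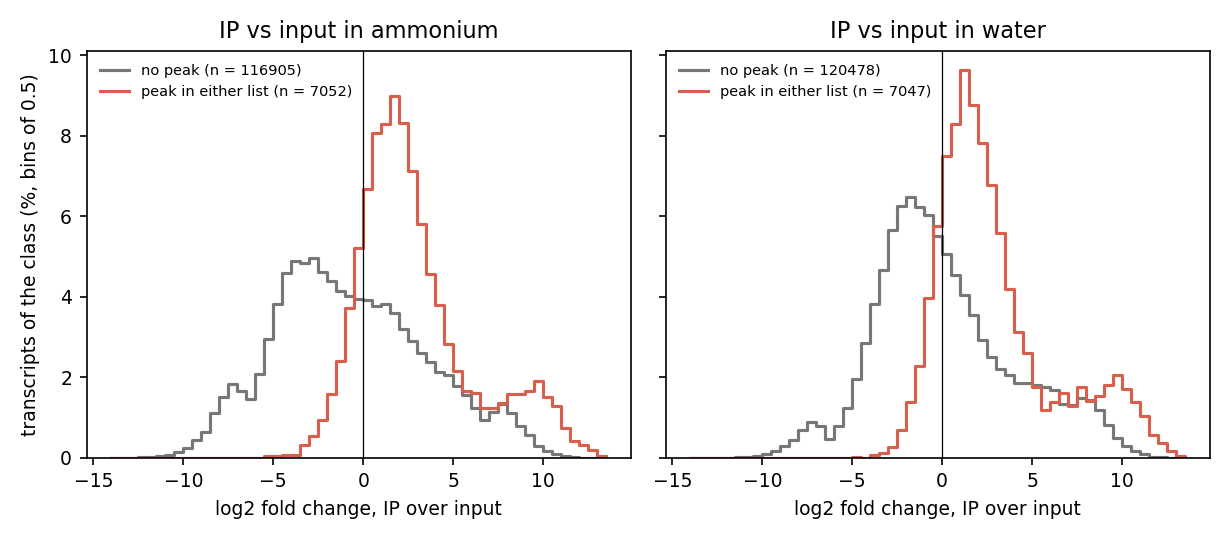
Distribution of fitted log2 IP/input over transcripts with and without a peak, in ammonium (left) and water (right), as the percentage of each class in bins of 0.5. Transcripts with a peak lie mostly above 0 in both treatments, and those without a peak spread widely to both sides, with medians of -1.06 in ammonium and -0.50 in water; values at the far ends include transcripts with 0 reads in a group.

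No transcript passed with edgeR for a change of the IP/input ratio with ammonium. Of 148273 transcripts tested with edgeR, 13109 (8.84%) had an unadjusted p under 0.05 and the smallest adjusted p was 0.556. The highest ranked in the lower direction was pp_141822, with a log2 change of -3.52 (SE 0.57, adjusted p = 0.556), whose input level was 2.74 ± 0.433 and 2.35 ± 0.251 CPM with water and ammonium. In the higher direction pp_133143 ranked first, with 0 reads in the 3 water IP libraries and 5 to 10 reads in each ammonium IP library, too few for a fold. DESeq2 called 93 transcripts (6 higher, 87 lower) and voom with sample weights 1, and 28 passed with edgeR without replicate 2 of the water IP. The median SE of the log2 change was 1.03, so changes of a few fold were not detectable for most single transcripts.

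As groups, transcripts with shared or ammonium-only peaks had a higher ratio with ammonium in the main fit, a call that did not hold in every alternative. The median log2 change was 0.34 for the 4966 with shared peaks (fry adjusted p = 0.0241) and 0.32 for the 1109 with ammonium-only peaks (fry adjusted p = 0.0241), against -0.22 for all transcripts. In camera with an estimated correlation both passed (adjusted p = 0.0483 and 0.0300), but the first was lost without replicate 2 of the water IP (adjusted p = 0.0801) and without replicates 1, 2 and 3 of the ammonium IP (adjusted p = 0.0685, 0.0619 and 0.0694), and the second without replicate 1 of the water IP (adjusted p = 0.141) and replicate 3 of the ammonium IP (adjusted p = 0.0589). The 1002 with water-only peaks had a median of -0.12 (fry adjusted p = 0.768). Without replicate 1 of the water IP the medians were 0.17 for shared peaks (fry adjusted p = 0.00635) and 0.20 for ammonium-only peaks (fry adjusted p = 0.0983), against -0.01 for all transcripts, so both lay closer to all transcripts than in the main fit. Without replicate 2 of the water inputs both calls were lost (fry adjusted p = 0.0542 for shared and 0.0508 for ammonium-only peaks), as with the filter of 50 reads in 3 libraries (adjusted p = 0.0614 for both). With library size scaling the medians were 0.073 and 0.044 beside -0.50 for all transcripts and neither passed (fry adjusted p = 0.195 and 0.587). Transcripts with water-only peaks then passed in fry as lower, although their median lay above that of all transcripts. The fry test is against 0 and this scaling lowers all transcripts. The loss thus does not show a smaller distance from the other transcripts, nor the gained call a larger one. With a block for each treatment and replicate number both were lost in fry (adjusted p = 0.0695 for both) and in camera with an estimated correlation (adjusted p = 0.0898 for shared and 0.0798 for ammonium-only peaks). No single member of the 3 groups passed in the main fit, also when adjusted over the transcripts with a peak alone. Without replicate 2 of the water IP, 1 transcript with water-only peaks was called lower, and 10 passed when adjusted over that group alone. The groups were defined by peaks from these libraries, so they are not independent of the counts.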

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

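The tests of sequencing depth, of scaling and of other splits of the libraries were chosen only after the results they concern were seen.

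The IP/input ratio differed between treatments for 2 of the 3 peak classes, by the test of the interaction in the main fit. The classes were defined by peaks from these same libraries, so they are not independent of the counts. A higher ratio with ammonium at ammonium-only peaks could follow in part from that choice. The median log2 change with ammonium was 0.34 at transcripts with shared peaks (fry adjusted p = 0.0241) and 0.32 at transcripts with ammonium-only peaks (fry adjusted p = 0.0241), against -0.22 for all transcripts; transcripts with water-only peaks did not pass (median -0.12, fry adjusted p = 0.768). The second call was lost without replicate 1 of the water IP, at a median of 0.20 (fry adjusted p = 0.0983), and the first passed at 0.17 (fry adjusted p = 0.00635); the median of all transcripts was then -0.01, so both classes lay closer to all transcripts than in the main fit. Both were lost without replicate 2 of the water inputs (fry adjusted p = 0.0542 and 0.0508) and with library size scaling, at medians of 0.073 and 0.044 beside -0.50 for all transcripts. With that scaling the water-only class passed in fry as lower, although its median lay above that of all transcripts. The fry test is against 0 and this scaling lowers all transcripts. The loss of the 2 calls thus does not show a smaller distance from the other transcripts, nor the gained call a larger one. With a block for each treatment and replicate number both were lost at nearly the same medians, 0.35 and 0.35 (fry adjusted p = 0.0695 for both). The filter of 50 reads in 3 libraries lost both calls in fry as well. In camera with an estimated correlation both passed in the main fit (adjusted p = 0.0483 for shared and 0.0300 for ammonium-only peaks). Each lost that camera call with the same block, and without some single IP libraries. Without the transcripts that had a group at 0 reads, the medians were 0.35 and 0.33, against -0.18 for all transcripts.

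Replicate 1 of the water IP lay nearer to the inputs than the other 5 IP libraries. The 2172 transcripts most strongly depleted in the ammonium IP kept 4.63% of their input share of reads in this library, against 0.716% and 1.23% in replicates 2 and 3, and the 6518 mildly depleted kept 32.7%, against 12.2% and 19.7%. Input RNA carried over in 1 fixed share is argued against as the whole reason. With replicate 3 as baseline, the share needed at mildly depleted transcripts was 4.73 times that at strongly depleted transcripts (16.2% against 3.44%). The multiple was higher with replicate 2 as baseline (23.4% against 3.94%). Replicates 2 and 3 also differed by more percentage points at mildly than at strongly depleted transcripts. A fixed share on top of such differences between libraries therefore stays open. Lower depth is argued against as well, since its total was 1.09 times the mean of the other 2. Weaker enrichment of the whole library stays open: at enriched transcripts its median log2 IP/input lay 0.11 below the lower of replicates 2 and 3 (2.88 against 3.14 and 2.99), less than those 2 differed from each other. Its shares of reads go with weaker enrichment. They were 29.7% on transcripts with a peak (32.9% and 32.8% in replicates 2 and 3) and 46.8% on those at least 4-fold higher in both treatments (57.2% and 52.6%). Both sets of transcripts were defined from these same libraries. No biological explanation was tested.

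With edgeR, 487 transcripts were called for ammonium in the input and 0 in the IP, where 10431 had an unadjusted p under 0.05 and DESeq2 called 316. Too few IP reads could account for part, as 55.2% (50.8 to 59.6) of the called transcripts had under 50 reads per IP library on average. That share was not computed over all tested transcripts. Of those called with 50 or more reads, 209 higher and 9 lower were tested in the IP and 0 passed. Reads under 50 thus do not account for the lack of calls at these. Whether more reads would have given calls there was not tested. Larger spread between IP libraries was expected to leave the size of the change intact; with all libraries the median ratio of IP to input change at the higher transcripts with 50 or more reads was 0.170 (0.0451 to 0.312), below the bound of 0.5 set beforehand. That bound was wrong because its interval was drawn over transcripts and left out the spread between libraries: without replicate 1 of the water IP the ratio was 0.690 (0.627 to 0.745), without replicate 2 it was -0.111 (-0.267 to 0.0714) and without replicate 3 it was 0.0975 (-0.0927 to 0.236), and omission of 1 ammonium IP library gave 0.0983 to 0.289. Relative to the median of all transcripts it was 0.835, -0.0364 and 0.439 without replicates 1, 2 and 3 of the water IP. The ratio was thus above the bound in 1 of 6 omissions and below it in the others, so spread stays open. A change of methylation at these transcripts, the biological alternative, stays open too. Their median log2 change of the IP/input ratio was -0.96, against -0.22 for all transcripts, and 1 of the 487, lower, passed with edgeR when p was adjusted over them alone; over all transcripts edgeR called 0 for the ratio (13109 with an unadjusted p under 0.05) and DESeq2 93. The input counts that chose these transcripts also enter the ratio, so a lower ratio at those higher in the input could follow from the choice. Only 334 of the 487 passed the count filter in the IP comparison. The median of -0.96 is not given here without single libraries. The IP change that enters it moved with the water IP: its median at the higher transcripts was 0.14 with all libraries. It was 0.72, -0.16 and -0.03 without replicates 1, 2 and 3 of the water IP.

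Most transcripts higher in the IP carried no peak: of 40190 higher in both treatments, 5172 (12.9%) had one. Too few IP reads per transcript for a peak are argued against as the whole reason. In the top 10% by IP reads, 32.5% (30.8 to 34.2) of the transcripts at least 4-fold higher in both had a peak. The share was 0.666% in the lowest 10% and 15.6% in the 10% below the top, so it was still rising. Transcript length and input reads were not considered, so coverage in that wider sense stays open. The scaling of IP against input stays open: 34986 transcripts were higher in both treatments with library size scaling, but it moved the median of all transcripts only from -0.30 to -0.80 in water and from -0.74 to -1.28 in ammonium, too little to decide where the transcripts called higher had medians of 4.05 and 3.42. The rules of the peak caller, reads shared between similar transcripts and a difference in how IP and input libraries were made, which would enter every IP/input fold, were not tested and stay open, and m6A outside the listed peaks is the biological alternative.

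Other splits of the 6 libraries of each comparison were fitted in the same way, with 10 splits each. The real split was the single one with as many calls in the input (487, highest other 0), for IP against input in water (87072, highest other 0) and in ammonium (107055, highest other 0), so 1 of 10 splits. For IP against input every other split mixed both kinds of library in each group. The 0 calls there were thus close to fixed in advance. For ammonium in the IP all 10 of 10 splits gave 0 calls, and so did all 10 of 10 relabellings for the change of the ratio. With 10 splits no share under 0.05 can be reached.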

How the results depend on the processing

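The voom fits and the adjustments over shorter lists were chosen only after the results were seen; all other alternatives were set before the data were examined. No called transcript changed sign under any alternative in which it was tested, except with library size scaling (113 of 87072 for IP against input in water and 783 of 107055 in ammonium). The counts of transcripts called for ammonium moved most. In the input (487), DESeq2 called 2843, no filter 2461, the filter of 50 reads in 3 libraries 252, voom 3060 and the fit of all 12 libraries 0; omission of 1 library gave 39 to 4921. In the IP (0), DESeq2 called 316, no filter 1863, the fit of all 12 libraries 879, voom 9 and adjustment over transcripts called in the input 33; omission of 1 library gave 0 to 34, above 0 only without replicate 2 of the water IP. For the change of the ratio (0), DESeq2 called 93, voom 1 and adjustment over transcripts called in the input 1; omission of 1 library gave 0 to 28, again above 0 only without that replicate. With the filter of 50 reads, which tests fewer transcripts, IP against input called 58044 in water and 69539 in ammonium. The shared spread of all 12 libraries lies between those of input and IP; the cause of the other differences was not tested.

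The overlap of peaks was 75.5% of water and 76.1% of ammonium peaks when an overlap of at least 50% of both peaks was required, and 83.2% of water transcripts had a peak in both lists. With library size scaling the median log2 IP/input in water was 1.37 for shared, 3.28 for water-only, 1.93 for ammonium-only and -1.002 for no peaks, and in ammonium 1.48, 2.79, 2.08 and -1.61. With the filter of 50 reads it was 2.52 for water-only and 1.96 for ammonium-only peaks in water, and 2.16 for shared, 2.20 for water-only, 2.31 for ammonium-only and -1.15 for no peaks in ammonium. Omission of 1 library gave -0.91 to -0.23 for no peaks in water, and in ammonium 1.94 to 2.10 for shared, 3.26 to 3.52 for water-only and -1.28 to -0.75 for no peaks. For the change with ammonium, library size scaling gave -0.41 at water-only (fry adjusted p = 0.0315), 0.044 at ammonium-only (adjusted p = 0.587) and 0.073 at shared peaks (adjusted p = 0.195), beside -0.50 for all transcripts. The filter of 50 reads gave 0.27 and 0.31 at ammonium-only and shared peaks (adjusted p = 0.0614 for both). Omission of 1 library gave 0.20 to 0.40 and 0.17 to 0.45; both calls were lost without replicate 2 of the water inputs (adjusted p = 0.0508 and 0.0542), and that of ammonium-only peaks without replicate 1 of the water IP (adjusted p = 0.0983).

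The replicate numbers gave no consistent pairing: over 4 pairs of groups, deviations of same-numbered libraries from their group means correlated at -0.06 to 0.11 across transcripts. In ammonium, all 3 correlations of input and IP were positive (0.0697 to 0.108) and each library correlated best with its own number; in the other pairs not every library did. With the replicate number as a block, 896 transcripts were called in the input, 8 in the IP, 77033 for IP against input in water, 103259 in ammonium and 0 for the change of the ratio. Under the block the correlation of input and IP changes was 0.293 and the median for no peaks in ammonium -1.13. With a block for each treatment and number, the medians were 0.35 at shared and 0.35 at ammonium-only peaks (fry adjusted p = 0.0695 for both).

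Among the named transcripts, the 4 called in the input lost the call only in the fit of all 12 libraries, and those called for IP against input kept it in all 15 alternatives each. The planned gene lists and cell type markers were not run, because the transcript IDs carry no gene names here. Of the 487 transcripts called in the input, 269 had under 50 reads per IP library, which limits what the IP can show for them.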

Other observations

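The test of IP/input against abundance-matched transcripts was set before its result was seen, and the counts of transcripts found in only 1 kind of library were chosen after the data were seen.

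Transcripts that rose with ammonium had fewer peaks and a lower IP/input ratio than tested transcripts of like abundance. Of the 440 higher transcripts, 18 (4.09%) carried a peak, where draws of tested transcripts of like abundance gave 10.3% on average (95% of draws 7.73 to 13.2; p = 1e-04 in a two-sided permutation test, the smallest that 10000 draws give, adjusted p = 1e-04). Their median log2 IP/input, averaged over treatments, was -3.56, against -1.30 in matched draws (95% of draws -1.68 to -0.92; p = 1e-04 in the same permutation test, adjusted p = 1e-04). The hypothesis tested was that responsive transcripts carry m6A more often than others, and both values lie in the opposite direction. The draws were not matched on IP reads, on which the calling of peaks depends (0.666% to 32.5% with a peak from the lowest to the top 10% by IP reads), so the share with a peak is no second, separate measure of m6A. The p-values treat transcripts as independent, which IDs that share reads are not, and input counts enter both the choice of the transcripts and their IP/input ratio, so a low ratio in ammonium could follow in part from the choice; with water alone the median was -2.89, and with ammonium alone -4.19.

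Some transcripts were found in the IP only. With 0 reads in all 6 inputs and at least 50 reads in each of the 6 IP libraries, 518 transcripts took 0.160% ± 0.0236 of the water IP reads and 0.131% ± 0.0432 of the ammonium IP reads (SD, n = 3), and 248 of them carried a peak. In reverse, 222 transcripts had at least 50 reads in every input and 0 in all 6 IP libraries.

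A set of 477 transcripts carried a peak yet were lower in the IP than in the input over their whole length in both treatments, against 5172 with a peak that were higher in both.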
